A study of Mus musculus with 18 samples.

How the data were processed

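Genomic DNA from tails of a sire, a dam and 7 progeny was hybridised against DNA of 1 reference male on 2-colour Agilent oligonucleotide arrays, with each animal on 2 arrays whose dyes were exchanged, per the labels. Per the file headers, Agilent Feature Extraction 12.1.0.3 produced the processed signal of each channel, an intensity that was background-subtracted and linearly dye-normalised per array, and the log10 ratio of both channels. The raw median intensity of spot and background is also given, per the file headers. The deposited value table holds log2 ratios of reference over animal. How the authors normalised it is not stated, and it correlated with the scanner ratio at 0.965 to 1 in size. Probe coordinates are on mm9, per the file headers.

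The log2 ratio of the processed signals was turned to animal over reference and centred on each array's median over autosomal probes. Control spots and spots marked as outliers by the scanner software were left out, and spots of the same probe were averaged. This gave 67022 probes, 48 on X and 3 on Y. The mean of both orientations was an animal's value, and the technical SD was the SD over the 9 animals of 50% of the difference between orientations. Arrays give no counts, and their number limits the precision. Slides 1 to 5 held the parents, progeny 1 and 2, progeny 3 and 4, progeny 5 and 6, and progeny 7. Slides 1 and 2 formed scan session 1, slides 3 and 4 session 2, and slide 5 session 3.

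Within runs of probes with gaps of at most 10 kb, the interval with the largest score was taken and its sides were searched again. The score was the size of the summed log2 ratios over the noise SD times the square root of the number of probes. A call needed a score of at least 6, at least 3 probes, a mean of at least 0.25 in size, and in each orientation the same sign and at least 50% of that threshold of 0.25. The null was the caller on 50% of the difference between orientations, after each probe's median over the 9 animals was removed. There the condition on each orientation could not fail, so the null was called more loosely than the animals. Calls of the same sign that overlapped were merged into regions. A progeny-only region was called in neither parent, and a calling progeny differed from each parent by at least 0.25 in both orientations.

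Tests used limma 3.58.1 in R 4.3.3 with Benjamini-Hochberg adjustment at 0.05, two-sided where a direction applies. Region means were fitted over all 18 arrays with animal and dye orientation as factors, each progeny against the mean of its parents, so the error was technical. Probes were tested on the 9 animal means for progeny against parents and for the family mean against 0, and on the 18 arrays for differences between animals with the F test. The pair of an animal was thus 1 replicate in the calls and in the tests on animal means, whereas in the tests on 18 arrays its arrays were the replicates. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. A single family was measured, so no test compares exposed with unexposed animals.

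Both methods were tested on simulated data. For copy number calls per animal, the caller searched 67022 probes, again with a condition on each orientation that could not fail. It found 100% of planted changes of -1 and of -0.6 at 3 to 30 probes. It found 98.3% to 100% of gains of 0.5. Gains of 0.3 over 3 probes were found in 32.5% at the noise of session 2 and in 94% at that of sessions 1 and 3. For probes differing between progeny and parents, 92% of 200 probes shifted by 0.5 among 66742 were found with 49 false calls, and 100% of those shifted by 1 with 50. For the family mean 100% were found at both sizes with 0 false calls. In both simulations on animal means each animal's values were shuffled over probes separately, so the simulated animals shared no signal beyond the planted shift. The 0 false calls therefore do not cover effects that the real animals share. For differences between animals 0% were found at 0.5, and 99% at 1 with 15 false calls. For region differences 100% were found over 750 simulated regions with 33 false calls at 0.5 and 22 at 1. In every test that made false calls, their share of all calls exceeded the nominal 5%.

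The regions named were fixed by rule before the data were examined. They are the 10 progeny-only regions with the largest mean in size in a calling progeny, the 10 parent-and-progeny regions with the largest mean over calling animals, up to 10 regions called in all 9 animals by number of probes, and 5 parents-only regions by mean. The 5 probes with the smallest p of each probe test were named too. Regions outside the rule are marked where they appear.

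Alternatives were normexp with an offset of 50, the deposited value table, loess, either orientation alone, dim or saturated probes left out, and other thresholds for mean, score, number of probes, gap and overlap. The ratio against the median of the 9 animals, slide as a random block and each animal left out in turn were also run. After the data had been seen, 4 more were added: 2 principal components removed, a score threshold above the null, both together, and session 2 left out. Normexp used median in place of mean spot signals, because the mean signals were not used here. The gene lists fixed beforehand, the antigen receptor marker check and gene names were not analysed here, since the gene table at hand is on another genome build.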

Results

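DNA from the tails of 9 mice of a single family was compared with DNA from 1 reference male of the same colony by array comparative genomic hybridisation, which reads the ratio of DNA copies at each probe. The family consisted of a sire, a dam and 7 progeny of the C57BL/6JNrs strain. Each animal was hybridised on 2 arrays with the dyes exchanged, which gave 18 arrays, and the mean of the dye-swapped pair was an animal's value. Where tests were fitted over the 18 arrays, the arrays of a pair were the replicates and the error was technical. The arrays were custom designs for a secondary screen: per the labels, their probes were packed around places that a first array had marked as aberrant, so the counts below describe those places and are not rates over the genome. The series title names males exposed to 0.05 mGy per day for 400 days, whereas its design text describes the male of this family as not irradiated. The sire's exposure is therefore left open here, and with 1 family no exposed group was set against an unexposed group.

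The arrays carried 67022 distinct probes, of which 63135 lay in 874 runs of at least 3 neighbouring probes, with a median spacing of 94 bp within runs. Between 98.7% and 99.8% of spots were well above background and none was saturated. The number of arrays limits the precision. The scanner's spread between adjacent probes was 0.096 to 0.128 on the arrays of scan sessions 1 and 3, and 0.148 to 0.179 on those of session 2, which held progeny 3 to 6. Values are log2 of animal over reference, and the ± beside a region value is the technical SD of an animal's mean over both dye orientations, taken over the 9 animals. Each animal is 1 biological sample, so this error does not cover differences between families.

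Probes on the sex chromosomes served as a check of the labels. The median over 48 X probes was -0.01 in the sire and 0.92 in the dam, both measured against a male reference. Progeny 1 and 2 had X medians of -0.01 and -0.01, and progeny 3 to 7 lay between 0.88 and 0.98. Of the 3 Y probes, A_67_P09496867 and A_67_P09496950 were well above background in the channel of the sire and of progeny 1 and 2 on both arrays. In progeny 3 to 7 they were so on neither array, and in the dam only the second was, on 1 array, which makes their ratios there bounds, not levels. The third, A_67_P09497617, was well above background on both arrays of all 9 animals, females included, so its detection did not separate the sexes.

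The first comparison asked where each animal differed from the reference. The interval caller made 1731 calls over the 9 animals, 1313 gains and 418 losses. The sire had 331 calls, the dam 206 and the progeny between 24 (progeny 2) and 308 (progeny 6). The caller on the dye-swap null, which holds no animal signal, made 450 calls. There were between 10 and 21 in the animals of sessions 1 and 3 and between 64 and 112 in those of session 2. For null calls the condition on each orientation could not fail, so their number is not directly comparable with the 1731. The longest null call spanned 12 probes and the highest null score was 24.3. By score, many calls of 3 or 4 probes in progeny 3 to 6 did not exceed the null. The 1731 calls merged into 757 regions. With a score threshold of 25, just above the null, 186 calls in 83 regions were left, 67 gains and 16 losses. Most of these gains had the sire highest, followed by the dam and progeny 1. Whatever both arrays of an animal share cancels in the null. This threshold therefore cannot screen out an effect common to both arrays of an animal.

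**Figure D1:**
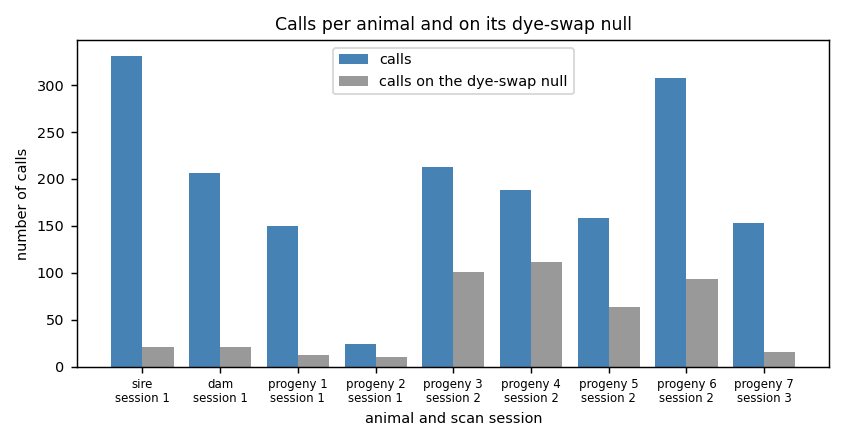
Number of calls in each of the 9 animals (blue bars) beside the number made on that animal's dye-swap null (grey bars), with the scan session under each name. On the null the condition on each orientation could not fail. The sire had 331 calls against 21 on its null, and the 4 animals of session 2 had the 4 highest null counts, 64 to 112.

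Progeny-only regions address the study's question of copy number changes that neither parent carries. The clearest was a loss in progeny 7 on chromosome 3 from 71236714 to 71245229 (mm9). Over its 29 probes progeny 7 read -1.01 ± 0.02, which is a linear ratio of 0.496 where loss of 1 of 2 copies gives -1.0 on the log2 scale. The sire read 0.04, the dam -0.06 and the other 6 progeny between -0.09 and -0.02. Progeny 7 differed from the parents' mean by -1.004 with a standard error of 0.04 (limma, adjusted p = 3.38e-07), and the other 6 progeny did not pass at this region. The nearest probes outside the loss, which read -0.06 on the left and -0.02 on the right as means of 3 probes, bound its extent between 8.52 kb and 19.8 kb. The loss was called in progeny 7, and in neither parent, in 28 of 29 alternative settings, the exception being the setting that left progeny 7 out.

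In all, 136 regions met the progeny-only rule, 104 gains and 32 losses, and a further 255 were called only in progeny but did not stand 0.25 apart from both parents in both orientations. Of the 136, 129 had 3 or 4 probes and only the chromosome 3 loss had 10 or more. That loss was also the only 1 left at the score threshold of 25. The count fell to 53 without the 4 animals of session 2 and rose to 233 without the sire. The split depended on the setting, with 51 gains and 94 losses against the median of the 9 animals, 115 and 125 on Cy5 alone, and 38 and 2 with normexp. Without dim probes it was 86 gains and 7 losses. The other 9 of the 10 progeny-only regions with the largest values had 3 or 4 probes and a technical SD of 0.09 to 0.34. Progeny 4 read -0.995 ± 0.23 at chromosome 7 from 47257271 to 47257872 and 0.66 ± 0.16 at the adjoining stretch from 47256470 to 47257005. Progeny 3, on the same slide, read 0.43 and 0.32 there. Progeny 3 read -0.82 ± 0.34 at chromosome 2 from 100379270 to 100379529. Progeny 6 had the largest value in 6 of them. It read 0.78 ± 0.19 at chromosome 18 from 67089737 to 67090151, 0.75 ± 0.18 at chromosome 11 from 53696498 to 53696625, where progeny 3 was called too at 0.44, and -0.63 ± 0.13 at chromosome 12 from 36147519 to 36147718. It also read -0.60 ± 0.19 at chromosome 5 from 111550321 to 111551483. At chromosome 2 from 173117829 to 173117961 and at chromosome 13 from 117033821 to 117033999 progeny 6 read 0.61 ± 0.12 and 0.61 ± 0.09, and progeny 3 and 7 were called there too, at 0.31 to 0.49. All 9 had scores under the highest null score. Against the parents' mean (limma), progeny 3 at chromosome 2 from 100379270 (adjusted p = 0.0677) and progeny 6 at chromosome 5 (adjusted p = 0.0547) did not pass. Nor did progeny 3 at chromosome 11 (adjusted p = 0.232). In the other regions and at chromosome 11 the animal with the largest value passed.

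**Figure D2:**
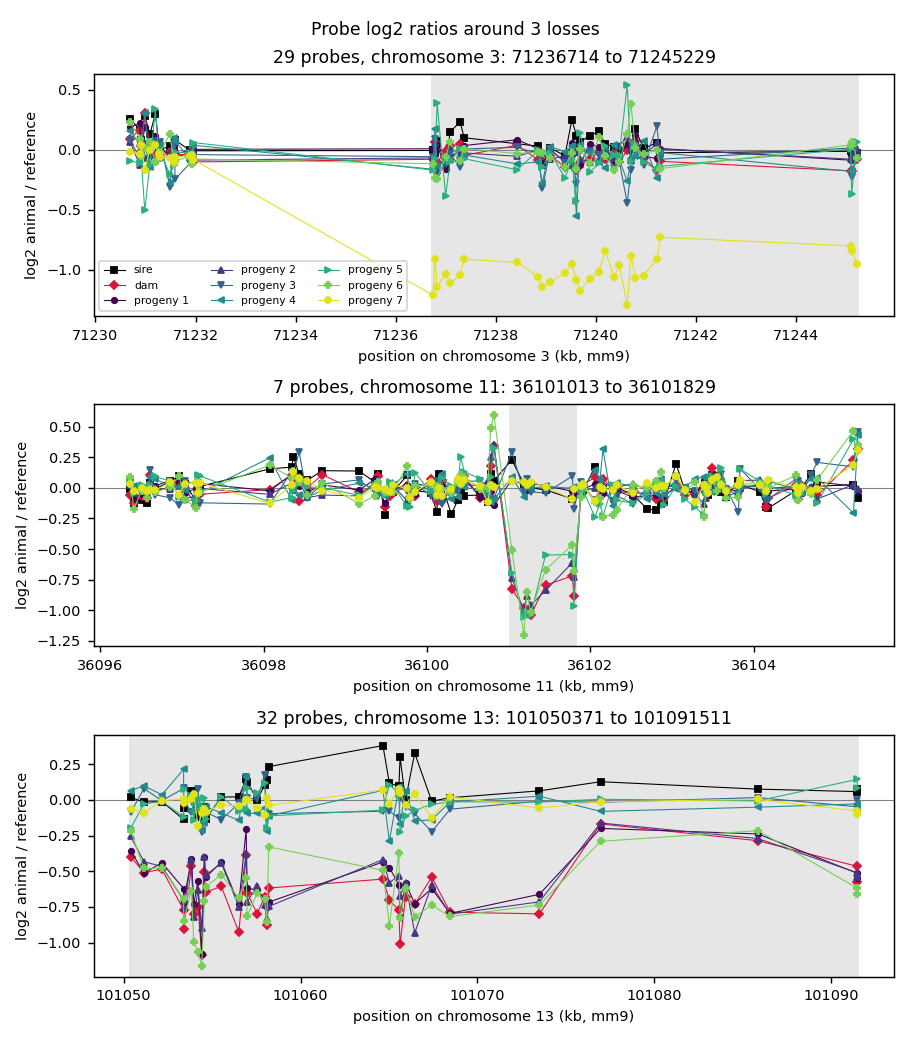
Log2 ratio of animal over reference (vertical axis) at each probe against its position in kb on mm9 (horizontal axis) for the 9 animals, around losses on chromosomes 3, 11 and 13; grey bands mark the called regions. At chromosome 3 progeny 7 alone runs near -1.01 over 29 probes, at chromosome 11 the dam and progeny 2, 5 and 6 lie between -0.89 and -0.77, and at chromosome 13 the dam and progeny 1, 2 and 6 lie between -0.66 and -0.57 as region means.

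Regions called in a parent and in progeny numbered 179, 150 gains and 29 losses. Some of them fell into separate levels that the dam and some progeny shared, and 3 such places follow. A gain on chromosome 4 spanned 156 kb from 101113754 to 101269545 in 3 neighbouring regions with 582 probes. Over its central 400 probes, from 101175993 to 101236503, the dam read 0.52, progeny 1 read 0.51 and progeny 6 read 0.50, with a technical SD of 0.00455. The sire and the other 5 progeny lay between -0.01 and 0.00. A loss of 32 probes on chromosome 13 from 101050371 to 101091511 read -0.65 in the dam, -0.57 in progeny 1, -0.59 in progeny 2 and -0.66 in progeny 6, each ± 0.01, against 0.06 in the sire and -0.05 to -0.03 in the others. A loss of 7 probes on chromosome 11 from 36101013 to 36101829 read -0.89 in the dam, -0.82 in progeny 2, -0.84 in progeny 5 and -0.77 in progeny 6, each ± 0.02, and between 0.01 and 0.03 in the sire and in progeny 1, 3, 4 and 7. Each of these kept its class in 28 of 29 alternative settings and lost it only without the dam. The chromosome 4 and 13 regions were chosen after their values were seen.

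**Figure D3:**
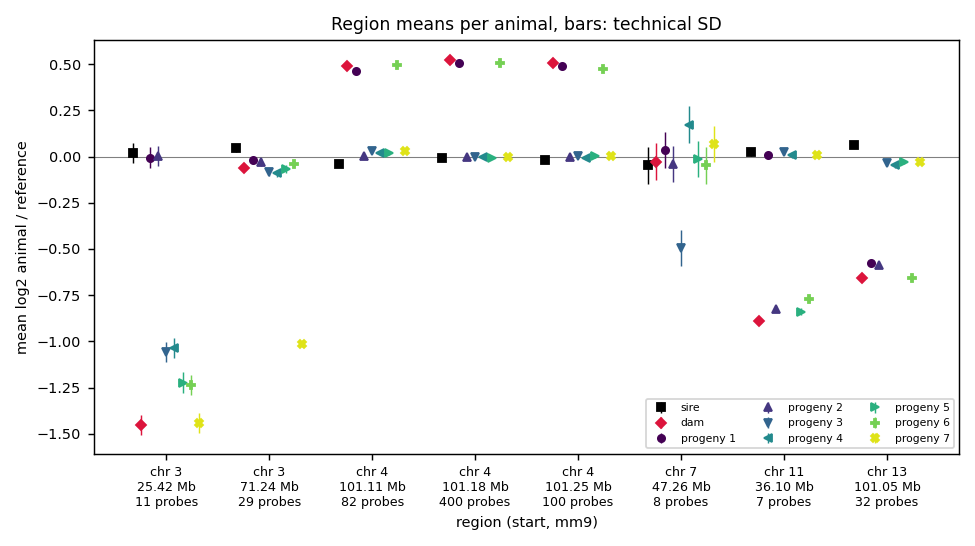
Mean log2 ratio of animal over reference (vertical axis) for each of the 9 animals in 8 regions of at least 5 probes whose values fell into separate levels; bars show the technical SD. At the 3 chromosome 4 regions the dam and progeny 1 and 6 sit at 0.46 to 0.52 and the other 6 animals at -0.04 to 0.03.

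The parent-and-progeny region with the largest mean was a loss of 11 probes on chromosome 3 from 25421508 to 25444229. It read -1.45 in the dam and -1.44 to -1.03 in progeny 3 to 7, against 0.02 in the sire and -0.01 and 0.00 in progeny 1 and 2 (technical SD 0.05). The remaining 8 of the 10 largest, all gains of 3 to 6 probes, shared a graded order instead of levels. They lay on chromosome 14 (62709352 to 62709779 and 13264938 to 13265388), chromosome 7 (83780442 to 83780812), chromosome 6 (6199855 to 6200093), chromosome 3 (68336924 to 68337652), chromosome 5 (91456562 to 91456724), chromosome 13 (100376393 to 100376766) and chromosome 17 (87551915 to 87552036). In each the sire was highest, at 0.97 to 1.21, followed by the dam at 0.58 to 0.80 and progeny 1 at 0.43 to 0.66. Progeny 7 lay between -0.03 and 0.10.

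Regions called in all 9 animals numbered 6, which at these thresholds were losses on chromosome 14 between 53708609 and 54328121, with 153 probes over 620 kb. The lowest values were -0.82 ± 0.05 (SD, n = 9) from 53750331 to 53764803 and -0.77 ± 0.03 from 53708609 to 53724678. The others read -0.50 ± 0.05 from 54116332 to 54134574, -0.37 ± 0.05 from 54264544 to 54328121, -0.37 ± 0.04 from 53961688 to 53992112 and -0.22 ± 0.03 from 54165356 to 54182168. The last is a mean over all 26 probes of the merged region, of which single calls covered at most 15 and averaged -0.55. Because all 9 animals were measured against the same reference mouse, a change in that mouse alone would give this reading as well. The reference's own spread was not measured.

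Parents-only regions numbered 181, 53 gains and 128 losses. The sire alone was called in 143 of them and the dam alone in 15. The 5 with the largest values were losses in the sire. It read -1.05 at chromosome 7 from 20028909 to 20029029, where the dam was called too at -0.42, and -0.97 at chromosome 8 from 109640023 to 109640230. It read -0.85 at chromosome 17 from 46848188 to 46848441, -0.81 at chromosome 11 from 69571437 to 69573053 over 11 probes, and -0.74 at chromosome 8 from 73965399 to 73965555. The dam lay between -0.42 and -0.15 and the progeny between -0.25 and 0.09 in these regions. Over all autosomal probes the sire also had the largest loadings of the 9 animals on the first and second principal components, 0.54 and 0.65, which held 41.5% and 17.4% of the variance.

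Each progeny was then set against the mean of its parents in every region with limma. Of 5299 tests, 2671 passed at an adjusted p of 0.05, 1436 higher and 1235 lower, from 243 in progeny 1 to 464 in progeny 3. The error is technical and the regions were selected on the same values, so these counts do not measure how many regions changed. In the regions called in all 9 animals only 1 test passed, for progeny 3. The share that passed was 50.4%, and 24.8% without the sire (1313 tests), where the majority turned, with 561 higher and 752 lower. Without the animals of session 2 it was 55.3%, or 1256 of 2271 tests. With 2 principal components removed, a setting that also takes real differences off, the share was 0.962%, or 51 of 5299 tests.

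Probe by probe, no probe passed between the 7 progeny and the 2 parents (limma, 0 of 67022 at an adjusted p of 0.05, and 10408 at an unadjusted p under 0.05). With 2 parents this does not show that no probe differed. Both parents shared a slide that held no progeny, so slide and generation were not separable within a slide. With slide as a random block the count was also 0. It was 897 with normexp background correction, 191 higher and 706 lower in progeny. It was 4 without the sire, all lower, 2738 without the dam, 1979 higher and 759 lower, and 414 without progeny 1, 50 higher and 364 lower. The 5 probes with the smallest p all had an adjusted p of 0.109 and lay on chromosomes 8 (A_67_P06659414), 2 (A_67_P00562720), 4 (A_67_P13063472), 18 (A_67_P21017276) and 3 (A_67_P12209480). Progeny minus parents was -0.42, -0.33, -0.71, -0.72 and -0.57 at these probes.

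Against 0, the mean of the 9 animals differed from the reference at 2567 probes, 1377 higher and 1190 lower, of which 744 had a mean of at least 0.25 in size, 159 of these lower. The 5 with the smallest p all lay in the chromosome 14 losses between 53712663 and 53758465. A_67_P19021120 read -0.95 ± 0.04 (SD, n = 9), A_67_P09562148 read -0.98 ± 0.05, A_67_P19021392 read -0.96 ± 0.05 and A_67_P19021194 read -0.85 ± 0.04, each at an adjusted p of 7.88e-11. A_67_P19021140 read -0.91 ± 0.05 at an adjusted p of 1.43e-10. The count was 1289 with slide as a random block and 122 without the animals of session 2, 6 higher and 116 lower. It was 446 to 1126 without the dam or without progeny 1, 3, 5, 6 or 7, so its size changed strongly when 1 of these animals was left out. Whether the smaller number of animals alone gives such a drop was not tested. The 9 animals are relatives measured against the same reference DNA, so their values are not independent. The p-values of this test treat them as independent and leave out the reference's own error.

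Animals differed from each other beyond the error between dye orientations at 1829 probes (limma F test), or 2.73% of those tested. Without the sire 844 passed, and without session 2, with its noisier arrays, 5768 passed. Of the 5 with the smallest p, 2 were Y probes (A_67_P09496867 and A_67_P09496950) and 1 was an X probe (A_67_P09342932). The other two were autosomal by the array's coordinates and divided the animals by the same pattern as the Y probes. A_67_P01905669 on chromosome 9 read -2.02 in the dam, -2.07 to -1.57 in progeny 3 to 7, and -0.02 to 0.17 in the sire and progeny 1 and 2. A_67_P11828393, inside the chromosome 3 loss that starts at 25421508, read -3.94 in the dam, -4.61 to -3.81 in progeny 3 to 7, and -0.11 to 0.00 in the sire and progeny 1 and 2. On 1 of the arrays of progeny 4 this probe was not well above background.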

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

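The tests of noise, dye channel and shared component for the progeny 7 loss were chosen after its values had been seen. Among the 31 named regions, the progeny were searched for an animal far from the other 6 by Dixon's ratio of gap to range, and 3 regions had one. Chance gives about 1 in 20 for regions not chosen on the values, but all 3 are among the 10 progeny-only regions named for their largest progeny value, so that rate does not apply to them.

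On chromosome 3 from 71236714 to 71245229 progeny 7 read -1.01, and the gap to the nearest other progeny took a share of 0.929 of the range. Noise between arrays was argued against by the score of 106.1, above the highest null score of 24.3, and a variant under single probes by 100% of the 29 probes lying below -0.5. A dye-channel effect was argued against by the weaker orientation, which read -0.9394 where calling required only the same sign and 50% of the 0.25 threshold, and a component shared with the short intervals by a mean of -0.8267 after 2 principal components were removed. A loss of 1 copy in the DNA of progeny 7 that neither parent's tail DNA carries is therefore a candidate explanation, found and tested on the same data. Progeny 7 was the only animal on its slide and in its session, parentage was not tested, and no independent assay was used here.

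On chromosome 7 from 47257271 to 47257872 progeny 4 read -0.995 over 3 probes, with a share of 0.602. On chromosome 18 from 67089737 to 67090151 progeny 6 read 0.78 over 3 probes, with a share of 0.745.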

How the results depend on the processing

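Settings with principal components removed, a score threshold above the null, both together, or session 2 left out were chosen after seeing the data. The deposited value table, loess, omission of dim probes, score thresholds of 5 and 8 and 50% reciprocal overlap kept every total they gave within 1.5 times. The progeny-only split moved from 104 gains and 32 losses to 110 and 17 with loess, 86 and 7 without dim probes and 77 and 16 at a score of 8. No spot was saturated, so that filter tested nothing. Normexp gave 1025 calls, 420 regions, 40 progeny-only regions (38 gains, 2 losses) and 897 probes differing between progeny and parents. Progeny-only regions were 240 on Cy5 alone (115 gains, 125 losses), where all regions were 311 gains and 315 losses against 506 and 251, and the family test gave 30482 probes on Cy5 and 31867 on Cy3 alone, where dye effects do not cancel. A mean threshold of 0.15 gave 12 regions in all 9 animals (5 gains, 7 losses) and 281 progeny-only regions, and 0.4 gave 803 calls, 368 regions and 22 progeny-only regions. At least 5 probes gave 1065, 446 and 31. Regions in all 9 animals were 3 with gaps up to 50 kb and 13 with gaps up to 2 kb. Against the median of the 9 animals there were 990 calls (550 gains, 440 losses), 0 regions in all 9 animals, 98 in a parent and progeny (60 and 38), and 51 gains and 94 losses among progeny-only regions. There were 360 gains and 352 losses among all regions.

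With 2 principal components removed there were 264 calls (128 gains, 136 losses), 219 regions (104 and 115), 0 in all 9 animals, 13 in a parent and progeny (7 and 6) and 40 progeny-only (22 and 18), with 51 region differences (33 higher, 18 lower), 0 family probes and 597 between animals. The score threshold above the null gave 186, 83, 2, 43 and 1 in the same order, and both together gave 28, 19, 0, 6 and 6. Removing components also takes real differences off and puts opposite ones into other animals. Without session 2 there were 864 calls, 501 regions, 53 progeny-only regions, 1256 region differences (of 2271 tests), 122 family probes (6 higher, 116 lower) and 5768 between animals. Slide as a random block gave 1289 family probes. Except where the setting's construction shows it, the cause was not tested.

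Leaving out each animal gave 1400 to 1707 calls, 615 to 756 regions, 6 to 8 in all animals left (with 1 gain without the dam and 2 without progeny 7), 146 to 179 in a parent and progeny, and 112 to 233 progeny-only regions. Region differences ranged from 1313 to 2577, probes between progeny and parents from 0 to 2738, family probes from 446 to 2274, and probes between animals from 844 to 2128. Without the sire there were 233 progeny-only regions, 1313 region differences (561 higher, 752 lower), 4 progeny-against-parent probes (all lower) and 844 between animals. Without the dam there were 2738 (1979 higher, 759 lower) and without progeny 1 there were 414 (50 and 364) progeny-against-parent probes, and the region differences without the dam were 1265 higher and 1312 lower. Family probes fell to 634 without the dam, and to 636, 1026, 446, 551 and 1126 without progeny 1, 3, 5, 6 and 7. With 1 parent left, that parent is assumed to vary like the progeny. No paired analysis was possible because the groups share fewer than 2 replicate numbers. The gene-list test and its alternatives were not run. Signal over background limited few probes, with 1113 dim probes, but leaving them out took progeny-only losses from 32 to 7.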

Other observations

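The tests in this part and their bounds were chosen after the results had been seen. The 3 other normalizations were planned as settings, but the test of order on them was chosen afterwards.

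Of the regions with at least 5 probes, 32 divided the animals into separate levels with a gap of at least 0.3. In 24 of them the sire alone stood apart, and 8 had another division. Outside the named regions, progeny 3 read -0.50 over 8 probes on chromosome 7 from 47258071 to 47258845, where the other 8 animals lay between -0.05 and 0.17. Its technical SD was 0.0981 and its score of 17.5 lay under the highest null score of 24.3. This stretch adjoins the regions in which progeny 4 was called. Progeny 3 and 4 shared slide 3, and their signs changed along these stretches. They read 0.32 and 0.66 from 47256470, 0.43 and -0.995 from 47257271, and -0.50 and 0.17 from 47258071. Whether the slide plays a part was not tested. At the chromosome 13 loss the 3 nearest probes on the left read -0.26 in the dam and -0.25, -0.24 and -0.20 in progeny 1, 2 and 6, so that edge is open. Left of the chromosome 11 loss the 3 nearest probes were raised in its carriers. They read 0.17 in the dam and 0.22, 0.13 and 0.36 in progeny 2, 5 and 6, against -0.09 to 0.02 in the other animals.

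Short gains followed the same order of animals at many places. Progeny 1 was the highest progeny in 126 of 150 parent-and-progeny gains on 19 chromosomes, which argues against separate variants passed on at each place. Membership rested partly on progeny 1 itself, and leaving that animal out gave 117 such gains. Under each of 3 other normalizations progeny 1 was the highest in at least 126 of the same gains. They had been selected under the main normalization, so this re-reading cannot decide whether the choice of normalization gave the order. A component of whole arrays that differs between animals may underlie most of these gains, but the following shares cannot settle it. The 2 components fitted only to probes outside every called region took up 95.69% of the sum of squares in the median gain. Of the 150 gains, 133 lay above 78.5%, the highest share in 6 regions of separate levels. Another 1, at 13.4%, lay under the 22.2% of chance. The lowest share in those 6 regions was 34.6%, so regions of separate levels passed chance too. They include parts of the chromosome 4 gain, which also count among the 150. Over all autosomal probes every animal loaded positively on the first component, from 0.14 to 0.54. A gain of any origin that is raised in several animals and highest in the sire would thus score high. Among 37 progeny-only gains called in a single animal of progeny 3 to 7, the mean of the 4 others lay above that of progeny 1 and 2 in 28. That is only just past the 75% set for scan session, with which it is consistent, and the regions are not independent. The dam's loading of 0.1676 on the second component lay above those of progeny 1 and 2. That component was led by the sire (0.65) and was not shown to be what these gains follow. The progeny-only rule leaves out gains that the dam shares, so this cannot decide whether sex plays a part.

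Losses that follow sex were weighed as well. The division of the 9 animals by sex held 6 losses and no other of the 84 divisions into 3 and 6 held more than 1, which is consistent with sex-linked copies of these sequences on the Y chromosome and not on X, where copies would read as gains in females. As first run, the test counted gains and losses together and came out the other way, with 6 by sex against 32 for the sire, dam and progeny 1, and it was restricted to losses, with a gap of 0.2, after that was seen. Losses called in progeny and chosen on the progeny alone, with progeny 3 to 7 below progeny 1 and 2, were the same 6, and the dam, scanned in session 1, lay nearer progeny 3 to 7 in all 6 and the sire in 0, which argues against scan session. Of the 32 probes in the 6 losses that divide all 9 animals by sex, 5 read below -2 in the dam, and no sequence match to the Y chromosome was analysed here.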
